A study of Canis lupus familiaris with 5 samples.

How the data were processed

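Single-cell RNA sequencing was performed on femoral bone marrow of 3 healthy dogs. Per the labels' protocols, marrow was flushed from femurs, red cells were lysed, and part of each suspension was loaded unsorted (whole marrow, 3 libraries). Viable CD34-positive cells were isolated by flow cytometry from 2 of the 3 marrows, numbers 2 and 3 (CD34-sorted, 2 libraries). CD34 is a surface glycoprotein of hematopoietic stem and progenitor cells and of early lymphoid precursors. The protocols required over 70% viability and under 25% neutrophils by flow cytometry for whole marrow, and 5000 cells were targeted per library. Droplet libraries (10x Genomics) tag the 3' end of each transcript with a unique molecular identifier (UMI), and read pairs of 150 bp were sequenced.

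The deposited files hold raw counts, whole numbers of UMIs per gene and barcode with no normalization, for 20257 features in each library. Of these features, 4432 carry only an Ensembl identifier in place of a symbol. Cell Ranger made the matrices; its version is 7.0.1 per the file headers and 7.1.0 per the submitters' processing notes. The genome build is CanFam 3.1 per the submitters' processing notes, and the annotation release is not given in the sources used here. Every deposited barcode held at least 500 UMIs. No genome of that build was used here, so genes are named by the symbols of the deposited files and no coordinates are given.

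Barcodes with at least 400 UMIs, at least 200 genes and at most 10% mitochondrial UMIs (13 mitochondrial genes) were kept. The UMI limit removed no barcode. Doublets were scored per library against simulated doublets. The number called followed an expected rate of 0.8% per 1000 cells, and 1046 cells were removed. Of 27953 barcodes, 23662 cells remained. Their counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours entered Leiden clustering at resolution 1.0. CD34, mitochondrial and ribosomal protein genes and all members of 18 gene lists were left out of clustering. CD34 was kept among the markers of the HSPC class (hematopoietic stem and progenitor cells), so it entered the naming of clusters. Markers of 19 cell classes were listed before the data were examined, as were the 18 gene lists, the rule for naming genes, the tests and most alternatives. The scoring rule that matched clusters to markers was set afterwards. It required at least 3 markers of a class at 2-fold or more above the median cluster, no other class with more markers among the 10 leading genes, and a lead of 0.5 on the log2 scale or more leading markers than the next class. Of 28 clusters, 22 received a name ending in "-like" and 6 stayed unnamed. Names rest on markers alone, since no cell annotation by the authors was used here.

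Cells are not replicates. UMI counts were therefore summed per library, or per library and class where at least 20 cells were present. Sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, TMM factors, low-count filter by group, robust fit) and Benjamini-Hochberg adjustment at 0.05. The sorted and unsorted libraries were compared over all cells and within HSPC-like (hematopoietic stem and progenitor cell-like) cells. Within whole marrow, late erythroid-like, neutrophil progenitor-like, mature neutrophil-like, monocyte-macrophage-like and pro-B or pre-B-like cells were each compared with HSPC-like cells with the library as a block; the other named classes were not compared here. Marrow 2 had 17 HSPC-like cells, so these class comparisons and the whole-marrow side of the HSPC-like comparison rested on marrows 1 and 3. Genes used for clustering or naming were left out of the class counts. An erythroid progenitor class was planned but no cluster met its marker rule, and that comparison was not run. Shares of cells were compared by an exact two-sided permutation test over the 10 splits of 5 libraries into 2 and 3, whose smallest possible p is 0.1. It treats the libraries as independent, though the sorted ones share dogs with whole marrows 2 and 3. Intervals of shares are exact binomial 95% intervals, a share of 0 is given with the limit that 3 counts allow, and both cover counting error only.

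Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. The 18 lists were cholesterol synthesis, DNA replication, endoplasmic reticulum folding and secretion, G2 and mitosis, glycolysis, hematopoietic cytokine receptors, heme synthesis and mitochondrial iron import, human stem cell genes, immediate early and heat shock, inflammatory cytokines and NF-kB targets, MHC class II presentation, oxidative phosphorylation, phagocyte NADPH oxidase, red cell membrane skeleton, ribosomal proteins, secondary and tertiary neutrophil granule proteins, type I interferon response, and V(D)J recombination. With an estimated correlation no list passed 0.05 in any of the 7 comparisons. Genes were named by rule: CD34, then the 10 largest rises and 10 largest falls (6 and 6 for class comparisons) among genes past the threshold. These needed a mean log2 CPM of at least 5, a symbol and no overlap between groups. From each list past its test, the 3 members with the smallest p could also be named, and some of them are not reported here. Folds against a group at 0 counts are lower bounds against 3 counts over the group. Where a group had 1 to 3 counts, the ratio of pooled counts is given with its exact 95% counting interval.

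Each count test was tested on simulated data with 200 genes changed. For all cells (12364 genes), 15% of 2-fold and 71% of 4-fold changes were recovered, with 12.2% false calls. Within HSPC-like cells (9312 genes) these were 8%, 52% and 10.4%. The class comparisons recovered 69% to 85% of 4-fold changes, with 1.85% to 5% false calls. Alternatives were RLE factors, DESeq2 1.42.0, no low-count filter, other mitochondrial, UMI and cell limits, doublets kept, resolutions 0.5 and 2.0, each library clustered alone, thinned counts, blocks, and leaving out each library. Fits with at most 20% mitochondrial UMIs, with at least 10 cells per sum, with HSPC-like sums thinned, and blocked list tests were chosen after seeing the data. Python 3.11.15, scikit-learn 1.9.0, leidenalg 0.10.2 and R 4.3.3 were used.

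The protocols name marrows 2 and 3 as the sources of the sorted cells, while the sorted libraries carry the title numbers 1 and 2. Sorted library 1 was paired with whole marrow 2 and sorted library 2 with whole marrow 3, by the nearest library numbers in the sample descriptions. As a check, the difference between the sorted libraries was correlated across genes with the difference between whole marrows 2 and 3. The correlation was 0.28 over all cells, 0.49 in pro-B or pre-B-like, 0.46 in neutrophil progenitor-like and 0.29 in HSPC-like cells. With the title numbers taken as pairs it was -0.14, -0.17, -0.25 and -0.16. Whole marrow 2 enters these 2 differences with opposite sign, so the negative values are not a separate check. With the difference between whole marrows 1 and 3 the correlation was 0.0084, 0.22, -0.0032 and 0.055 in the same order.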

Results

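The 5 libraries profiled canine hematopoiesis in unsorted bone marrow of 3 dogs and in CD34-sorted cells of 2 of the same dogs. Total UMI counts were 54074420, 46114431 and 47219133 in whole marrows 1 to 3, and 62188030 and 70169186 in CD34-sorted libraries 1 and 2. After filtering, 6861, 4414 and 4196 whole-marrow cells and 4556 and 3635 sorted cells were kept. Over all classes together, the median was 11390 and 14320 UMIs per cell in sorted libraries and 2589, 3577 and 4231 in whole marrow. Within HSPC-like cells it was 13570 and 14890 in sorted libraries and 15020, 18310 and 23720 in whole marrow. The median mitochondrial share of kept cells was 6.11% and 7.82% in sorted libraries and from 1.05% to 1.71% in whole marrow. In HSPC-like cells alone this share was 5.97% and 8.27% in sorted libraries and 7.36%, 6.88% and 8.65% in whole marrows 1 to 3. Mitochondrial limits removed most from sorted library 2 (22.9% of barcodes) and whole marrow 3 (16.5%).

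Clustering without CD34 separated 11 named classes. CD34 was among the markers that named HSPC-like cells and among the leading genes of cluster 24. The share of HSPC-like cells and their CD34 level are therefore not fully independent of the naming. HSPC-like cells (clusters 1 and 24) were led by TFPI and NRIP1, and FCER2 and APOC1, markers listed for other classes, were also among the leading genes of cluster 1. Neutrophil progenitor-like cells formed cluster 2, led by MPO, and cluster 8, led by SLPI and ELANE. Mature neutrophil-like cells formed clusters 0, 4, 5, 7, 13 and 17. Pro-B or pre-B-like cells formed clusters 3, 10, 14 and 19, with VPREB1, PAX5 and RAG1 among the leading genes. EPX, an eosinophil gene, was among the leading genes of the basophil or mast-like cluster, and FCN1, a myeloid gene, was among those of the 23 endothelial-like cells beside KDR.

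The first comparison asked which marrow cells carry CD34, by setting the make-up of sorted libraries against whole marrow. Sorted libraries consisted mainly of pro-B or pre-B-like cells (42.9% ± 2.20 SD, n = 2; whole marrow 2.12% ± 0.880, n = 3), HSPC-like cells (23.5% ± 4.22 against 0.418% ± 0.0506) and neutrophil progenitor-like cells (19.4% ± 1.12 against 7.82% ± 0.888). Plasmacytoid dendritic-like cells made up 2.81% ± 0.429 of sorted and 0.446% ± 0.162 of whole-marrow cells. HSPC-like cells were thus 56.2-fold and pro-B or pre-B-like cells 20.2-fold more frequent after the sort. Whole marrow held 47.2% ± 12.3 mature neutrophil-like, 6.97% ± 1.43 monocyte-macrophage-like, 6.95% ± 2.30 late erythroid-like, 1.97% ± 0.283 mature B-like and 1.28% ± 0.333 plasma-like cells. In sorted libraries these shares were 0.0907%, 0.0907%, 0.0247%, 0 and 0.0138%. Endothelial-like cells were 4.88-fold more frequent after the sort (0.0411% ± 0.0265 of whole-marrow cells). This fold rests on 12 and 5 sorted cells and on 2, 1 and 3 cells of whole marrows 1 to 3. The exact interval of sorted library 2 overlapped those of whole marrows 1, 2 and 3, and that of sorted library 1 overlapped that of whole marrow 3. Basophil or mast-like cells were 0.223% ± 0.191 and 0.840% ± 0.393, and the interval of sorted library 2 overlapped those of whole marrows 1 and 3.

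Counting intervals aside, the shares of sorted and unsorted libraries did not overlap in any of the 11 named classes, where chance gives no overlap in 20% of cases. With each library clustered alone, 8 of 15 named classes did not overlap. In that setting a class not named in a library counted as 0, and whole marrow had no named HSPC-like cells. A lack of overlap there can therefore come from naming. Each difference except that of basophil or mast-like cells had the smallest p the exact permutation test allows (p = 0.1, adjusted p = 0.11 over the 11 classes; basophil or mast-like p = 0.2, adjusted p = 0.2), so the design could not pass 0.05. The neutrophil progenitor-like difference turned with the clustering: it was 11.6 percentage points at resolution 1.0, -5.68 points with coarser clusters (resolution 0.5) and -0.299 points with each library clustered alone. Basophil or mast-like cells likewise moved from -0.617 to 10.8 points at resolution 2.0.

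**Figure D1:**
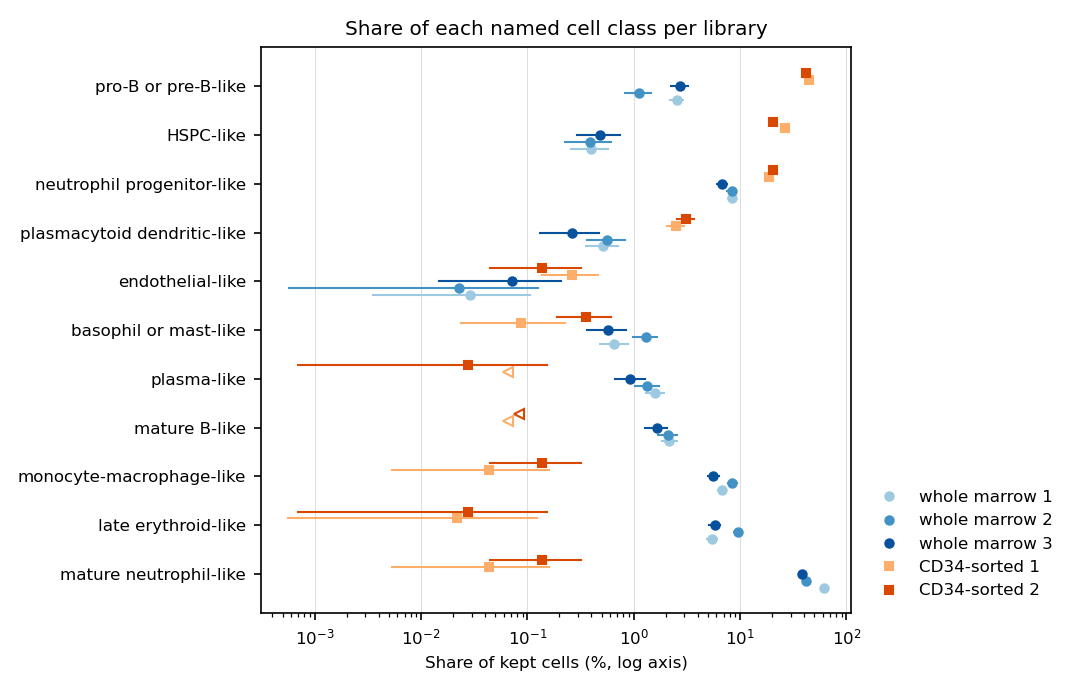
Share of kept cells in each named class (x axis, percent, log axis) per library, with exact binomial 95% intervals as bars; open triangles mark a share of 0 at the limit that 3 counts allow. HSPC-like cells lie at 23.5% on average in the CD34-sorted libraries (squares) and at 0.418% in whole marrow (circles).

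Different clusters made up the neutrophil progenitor-like class on either side of the sort. Cluster 2, led by MPO (myeloperoxidase of primary granules), held 18.6% and 20.1% of sorted cells and 0.810% to 1.27% of whole-marrow cells. Cluster 8, led by SLPI and ELANE (neutrophil elastase), held 5.98% to 7.29% of whole-marrow cells and 0.0220% and 0.0825% of sorted cells. Unnamed clusters held 10.3%, 24.8% and 36.8% of cells in whole marrows 1 to 3 and 7.40% and 13.9% in the sorted libraries. Cluster 6, which scored highest for mature neutrophils but had PADI3, listed as an eosinophil marker, among its leading genes, was 10.7% ± 8.80 of whole-marrow and 0.0219% of sorted cells. Cluster 15, led by LTB, PAX5 and MS4A1, was 5.28% ± 6.72 of whole-marrow and 0.135% of sorted cells.

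CD34 itself stood at 384 and 218 counts per 1e6 UMIs (CPM) in the sorted libraries and at 17.4, 13.7 and 13.5 in whole marrows 1 to 3. The all-cell log2 fold change was 4.06 ± 0.29 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000909). Within HSPC-like cells its level was 521 and 442 CPM after the sort and 411, 579 and 469 without it. In neutrophil progenitor-like cells it was 266 and 203 against 33.7, 38.5 and 35.2. In pro-B or pre-B-like cells it was 555 and 184 against 284, 344 and 36.5. The clusters of this class differed between libraries: cluster 19 held 25 of 2027 and 216 of 1504 of its cells in sorted libraries 1 and 2, and 19 of 174, 12 of 49 and 87 of 114 in whole marrows 1 to 3. Thinned to 1000 UMIs per cell, 40.7% and 36.4% of sorted HSPC-like cells and 33.3%, 41.2% and 60.0% of whole-marrow ones held a CD34 UMI (27, 17 and 20 cells in whole marrow). Unthinned shares were 97.8% and 98.7% against 92.6%, 100% and 90%. In mature neutrophil-like cells of whole marrow, which should lack CD34, the thinned share was at most 0.125% and the unthinned share at most 0.162%, with a median of 1875 to 4789 UMIs per cell against 15020 to 23720 in HSPC-like cells. As the gene of the gate and a marker used to name HSPC-like cells, CD34 is a check of the labels and no finding.

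**Figure D2:**
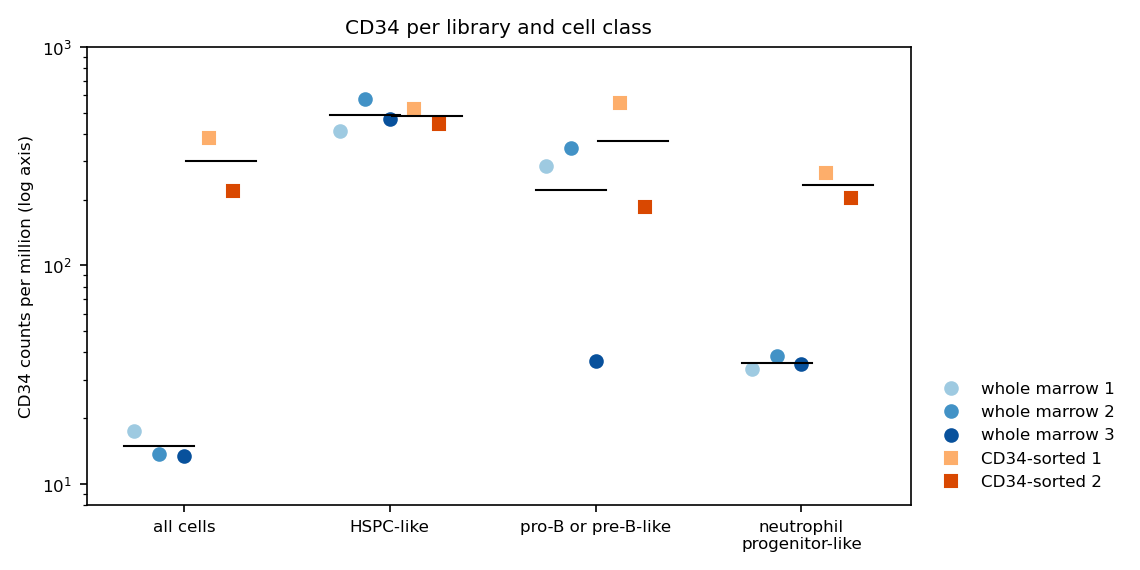
CD34 CPM (y axis, log axis) over all cells and in 3 cell classes; circles are whole-marrow and squares CD34-sorted libraries, and black lines are group means. Over all cells the sorted libraries lie at 384 and 218, above 17.4 in the highest whole marrow, while in HSPC-like cells both groups lie between 411 and 579.

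Over all cells, sorted libraries had more transcripts of human stem cell genes and of the early B-lineage genes DNTT and VPREB1, and far fewer of neutrophil granule and red cell skeleton genes. Beside CD34, the largest rises were SULT1B1, a sulfotransferase (205.9 ± 35.6 against 9.85 ± 4.54 CPM, SD, n = 2 and 3; log2 fold change 4.39 ± 0.47 SE), CLEC3B, which encodes tetranectin (4.10 ± 0.99), DNTT, the terminal transferase of antigen receptor joining (3.85 ± 0.51), and DPEP1, a dipeptidase (3.72 ± 0.60). VPREB1 of the surrogate light chain (3.26 ± 0.64), ASNS, asparagine synthetase (3.23 ± 0.44), SOX4 (3.13 ± 0.67), ALPL, alkaline phosphatase (2.94 ± 0.22) and EVA1B (2.82 ± 0.25) followed. ALPL had been listed as a marker of mature neutrophils and was among the genes leading cluster 2. The adjusted p of these genes ranged from 0.000909 to 0.0290 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CLEC3B, DPEP1, VPREB1 and SOX4 lost significance without either sorted library, SOX4 also without whole marrow 2, and CLEC3B also without whole marrow 2, without whole marrow 3 or without the low-count filter.

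The largest falls were C30H15orf48, MIOX (myo-inositol oxygenase, -10.72 ± 0.88), HBM (hemoglobin mu, -10.55 ± 1.69), HEMGN (-10.43 ± 0.92), PGLYRP1 (-10.37 ± 0.49), ALAS2, the erythroid enzyme that starts heme synthesis (-10.26 ± 0.93), S100A12 (-9.94 ± 0.50), AHSP, the alpha-hemoglobin chaperone (-9.89 ± 0.31), LCN2 (-9.62 ± 0.90) and MMP8, neutrophil collagenase (-9.50 ± 0.18). C30H15orf48 had 3 counts in sorted and 11693 in whole-marrow libraries, a ratio of 4108 with a counting interval of 1406 to 19925. MMP8 lay at 0.316 ± 0.0120 CPM in sorted libraries and at 230.1 ± 8.41 in whole marrow. HBM lost significance with the dog as a block.

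The gene lists moved with these lineages. Of 13 neutrophil granule protein genes tested, 12 fell and 0 rose, with a median log2 fold change of -8.89, among them CD177 (-8.89 ± 0.29) and LTF, lactoferrin (-7.46 ± 0.29). Of 17 red cell membrane skeleton genes, 14 fell and 1 rose (median -4.60), with RHCE at -7.69 ± 0.26 and SPTB, a spectrin chain, at -7.56 ± 0.34. Of 18 heme synthesis and iron import genes, 13 fell (median -2.21), such as CPOX (-3.07 ± 0.23). Among 21 human stem cell genes, 15 rose and 2 fell (median 2.28), such as ADGRG1 (3.55 ± 0.25) and HOXA9 (3.43 ± 0.25). Of 50 G2 and mitosis genes, 27 fell and 0 rose (median -0.73), including AURKA, a spindle kinase (-1.40 ± 0.12) and LBR (-1.61 ± 0.15). Ribosomal protein genes were higher (11 of 54 rose, median 0.35). Adjusted over the list alone, 12, 14, 14 and 31 genes fell in the granule, skeleton, heme and mitosis lists, 15 stem cell genes rose and 0 ribosomal protein genes did. Camera adjusted p were 9.28e-11 for granule proteins, 1.05e-07 for the skeleton, 6.21e-07 for heme, 0.000317 for stem cell genes, 5.12e-08 for G2 and mitosis and 0.000319 for ribosomal proteins. For ribosomal proteins the adjusted p = 0.533 with an estimated correlation, and for each of the other 5 lists the adjusted p = 0.269 with an estimated correlation.

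Inflammatory and phagocyte genes were lower too. Of 16 inflammatory genes 8 fell and 0 rose (median -1.60), with the neutrophil chemokine CXCL8 at -9.40 ± 0.82 and PLAUR at -6.68 ± 0.34, and 4 of 7 NADPH oxidase genes fell (median -2.15), including CYBB (-3.55 ± 0.27). Glycolysis genes fell in 9 and rose in 6 of 20 cases (median -1.03, PFKM -4.31 ± 0.18). Cytokine receptors fell in 10 and rose in 4 of 22 (median -1.32), with KIT, the stem cell factor receptor, up by 2.61 ± 0.15 and CSF2RA at -3.83 ± 0.25. Oxidative phosphorylation genes fell in 16 of 55 (median -0.32) and endoplasmic reticulum folding genes in 7 of 29 (median -0.30). Over the lists alone 9, 5, 11, 13, 16 and 2 genes fell and 0, 1, 6, 5, 0 and 0 rose. Camera adjusted p in the same order were 0.000317, 0.00880, 0.0309, 0.0154, 0.00267 and 0.0351. The folding list had adjusted p = 0.176 with the dog as a block. With an estimated correlation these lists had adjusted p = 0.269, adjusted p = 0.321, adjusted p = 0.441, adjusted p = 0.269, adjusted p = 0.321 and adjusted p = 0.584. No list-wide shift passed the camera test for cholesterol synthesis (2 rose, 1 fell of 20, adjusted p = 0.899), V(D)J recombination (1 and 1 of 12, 0.864), DNA replication (5 and 9 of 41, 0.284), MHC class II (1 and 3 of 12, 0.473), immediate early (0 and 5 of 18, 0.418) or interferon genes (1 and 2 of 22, 0.939). Cholesterol synthesis genes had a median of -0.04 and a mean of 0.07 beside an upward camera test.

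In all, 1925 genes were higher and 2147 lower among 12364 tested (edgeR quasi-likelihood test, Benjamini-Hochberg; 5548 at an unadjusted p under 0.05, 3 residual degrees of freedom). These sums mix cell classes, so they carry the shift in class shares. The count fell to 1698 without sorted library 1 and 1928 without sorted library 2, which each leave 1 sorted library assumed to vary like whole marrow.

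**Figure D3:**
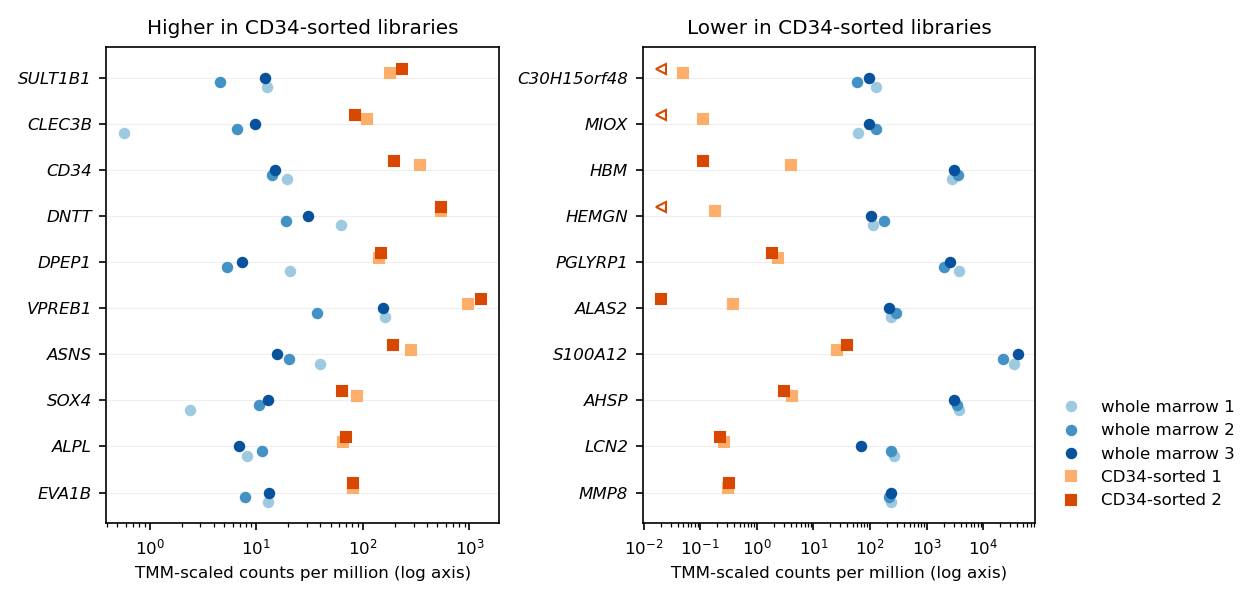
TMM-scaled CPM (x axis, log axis) of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) over all cells; circles are whole-marrow and squares CD34-sorted libraries, and open triangles mark libraries at 0. SULT1B1 lies at 205.9 on average after the sort and 9.85 in whole marrow, and MMP8 at 0.316 and 230.1.

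The second comparison asked whether HSPC-like cells differ with the sort. They contained 1208 and 747 sorted cells and 27 and 20 cells of whole marrows 1 and 3. The sorted cells came from marrows 2 and 3, so the sort cannot be told fully apart from the dog here. Only 6 genes differed among 9312 tested, all lower in sorted cells, and all but 1 of them symbols of neutrophils or red cells. SLPI, a protease inhibitor of neutrophil granules, had a log2 fold change of -6.28 ± 0.35 and CAMP, cathelicidin, of -8.66 ± 0.51 (both adjusted p = 0.000456, edgeR quasi-likelihood test with Benjamini-Hochberg). ELANE stood at -4.87 ± 0.53, HBM at -6.52 ± 0.58, AHSP at -6.92 ± 0.67 and the feature ENSCAFG00000032615, which leads the late erythroid-like cluster, at -5.73 ± 0.47. All but SLPI and CAMP were named after their values were seen. SLPI lay at 163 and 110 CPM in whole-marrow HSPC-like cells and at 2.09 and 1.31 in sorted ones. SLPI and CAMP lost significance at resolution 2.0 and with doublets kept, and CAMP also with at least 10 cells per sum. Of the 6 calls, 3 were kept in each of the first 2 settings, 2 (SLPI and CAMP) without whole marrow 1, and 4 without whole marrow 3 or either sorted library. CD34 differed by 0.21 ± 0.18 (adjusted p = 0.897).

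As sets, cell cycle lists lay lower and stem cell and immediate early lists higher in sorted HSPC-like cells, though no single member passed the test. The 49 G2 and mitosis genes had a median log2 fold change of -0.80 (CKAP2L -2.11 ± 0.48, CENPE -1.49 ± 0.34, AURKB -1.26 ± 0.32) and the 40 DNA replication genes of -0.43 (CLSPN -1.20 ± 0.24). The 18 immediate early and heat shock genes had a median of 1.43 (JUND 1.47 ± 0.66), the 19 stem cell genes of 0.78 (HOXA7 1.39 ± 0.44, MEIS1 1.08 ± 0.41, THY1 -1.30 ± 0.54) and the 20 interferon genes of 0.58 (IFI44 0.96 ± 0.43). Of 6 granule protein genes 2 fell, median -5.80. Adjusted over the list alone, 5 granule genes fell, 1 DNA replication gene fell, 1 immediate early gene rose and 0 genes of the other 3 lists changed. Camera adjusted p were 7.58e-12 for G2 and mitosis, 4.27e-06 for DNA replication, 0.00661 for immediate early, 0.0116 for stem cell, 0.0170 for interferon and 6.46e-08 for granule genes. For each of these 6 lists the adjusted p = 0.513 with an estimated correlation. With the dog as a block and at least 10 cells per sum, the stem cell and interferon lists had adjusted p = 0.662 (0.0855 and 0.723 without the block), and the interferon test turned downward. MEIS1 then had a log2 fold change of -0.10.

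Median, mean and camera test differed in sign for folding genes (-0.01, 0.24, down), for red cell skeleton genes (0.00, -0.07, up) and for V(D)J genes (0.00, -0.04, down), none past the threshold. At an unadjusted p under 0.05, 566 genes differed, and DESeq2 called 31. The count was 11 without whole marrow 1, 57 without whole marrow 3, 55 without sorted library 1 and 71 without sorted library 2. With at least 10 cells per sum, which adds whole marrow 2, the count was 53 of 4336 tested with the dog as a block and 7 of 4336 without it. Of the 53 genes 7 were higher in sorted cells, as were 47 of 135 without the low-count filter and 1 of 31 in DESeq2. All 7 without the block and all 13 at resolution 2.0 were lower. The whole-marrow sums hold 47 cells. Cluster 24 held 10 of 27 and 2 of 20 of them in whole marrows 1 and 3, and 113 of 1208 and 26 of 747 HSPC-like cells in sorted libraries 1 and 2. Without sorted library 1, the immediate early median was 0.53 against 1.47 with all 4 libraries (18 genes, no low-count filter). It was 0.84 at resolution 2.0 (10 genes), 0.84 with doublets kept (11 genes), and with at least 10 cells per sum 0.86 without and 0.74 with the dog as a block (10 genes).

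The following comparisons follow differentiation from HSPC-like cells within whole marrows 1 and 3. Each has 2 library pairs and 1 residual degree of freedom, so the spread of a gene was taken mainly from other genes of like abundance. Adjusted p were computed with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over genes not used to define cells.

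In late erythroid-like cells, genes of the red cell membrane, heme synthesis, mitochondrial respiration and mitosis rose, and MHC class II and stem cell genes fell. The largest rises had 0 counts in HSPC-like cells: MUC13, a membrane mucin (at least 60.4-fold higher), PKLR, red cell pyruvate kinase (at least 40.7-fold), ANK1, ankyrin of the red cell skeleton (at least 39.4-fold), PFKM, phosphofructokinase (at least 38.5-fold), TSHB, the beta chain of thyroid-stimulating hormone (at least 34.8-fold) and ERMAP, an erythroblast membrane protein (at least 33.9-fold). The largest falls were DNTT (log2 fold change -8.58 ± 0.32), SLA (-7.00 ± 0.24), SEPTIN6 (-6.26 ± 0.22), DLA-DRA of MHC class II (-6.23 ± 0.28), the actin-binding CORO1A (-5.93 ± 0.28) and GSN, gelsolin (-5.79 ± 0.28). CD34 was lower by a log2 fold change of -9.96 ± 0.30.

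Of 17 red cell skeleton genes 14 rose and 0 fell (median 6.70, or 4.42 with 5 genes at 0 counts set to their bound), such as the water channel AQP1 (7.23 ± 0.35). Of 18 heme genes 14 rose (median 4.08, or 2.91 with 2 genes at their bound), including ALAD (4.30 ± 0.22) and ALAS2 (18183 against 3 counts, ratio 263.5, counting interval 90.2 to 1278). G2 and mitosis genes rose in 43 of 50 cases (median 1.45, MKI67 2.19 ± 0.19) and DNA replication genes in 20 of 41, with 1 fall (median 0.77, RRM2 3.07 ± 0.26). Oxidative phosphorylation genes rose in 37 of 53, with 1 fall (median 0.78, ATP5IF1, the ATP synthase inhibitor, 2.73 ± 0.17). MHC class II genes fell in 9 of 11 (median -4.16). Stem cell genes fell in 7 of 11 and rose in 2 (median -3.80, MSRB3 -8.16 ± 0.52). Cytokine receptors fell in 6 of 9 (median -2.57, FLT3 -8.11 ± 0.57), while EPOR, the erythropoietin receptor, rose (6.22 ± 0.38). Over the lists alone 14, 15, 43, 23, 43, 0, 2 and 1 genes rose and 1, 0, 0, 1, 1, 9, 7 and 7 fell. Camera adjusted p were 2.39e-06, 1.18e-07, 1.16e-07, 0.000781, 2.39e-06, 3.57e-05, 0.00944 and 0.00350. In the same order the lists had adjusted p = 0.584, adjusted p = 0.584, adjusted p = 0.677, adjusted p = 0.584, adjusted p = 0.677, adjusted p = 0.584, adjusted p = 0.677 and adjusted p = 0.600 with an estimated correlation. Signs differed for glycolysis (median -1.26, mean 0.26, test down), immediate early (0.07, -1.23, down) and ribosomal protein genes (0.01, 0.01, down), none past the threshold. In total 1635 genes rose and 1125 fell of 7365 (3306 at an unadjusted p under 0.05), against a median shift of all genes of 0.11. MUC13, PKLR, ANK1, TSHB and ERMAP lost significance in DESeq2, and MKI67 without a block. DESeq2 called 1483 genes, the fit without a block 1527 and sums thinned to the same total of UMIs 1514 of 3675 tested. Cluster 9 made up this class and scored 5.024 for late erythroid cells and next, 1.969, for erythroid progenitors, which no cluster was named for. Which of its cells carried the cell cycle transcripts was not tested, so their rise cannot be assigned to late erythroid cells.

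Neutrophil progenitor-like cells had higher granule protein, NADPH oxidase, secretory pathway and respiration genes than HSPC-like cells, and lower stem cell, MHC class II and interferon genes. Cluster 8 held 500 of 571 of these cells in whole marrow 1 and 251 of 285 in whole marrow 3. CHI3L1, a chitinase-like granule protein, was at least 26.9-fold higher than in HSPC-like cells, where it had 0 counts. SLPI rose by 10.22 ± 0.50 and CAMP by 8.23 ± 0.38 on the log2 scale. TNFSF13, the cytokine APRIL, had 1667 counts against 1 (ratio 171, counting interval 30.6 to 6752), LCN2 1451 against 1 (149, 26.6 to 5877) and RASL11A 1241 against 2 (63.6, 17.6 to 525.6). The largest falls were DNTT (-3.40 ± 0.20), HLA-DQB2 (-2.92 ± 0.20), DLA-DRA (-2.51 ± 0.22), GYPC (-2.32 ± 0.23), the co-repressor CBFA2T3 (-2.27 ± 0.23) and LRRC71 (-2.19 ± 0.24). CD34 had a log2 fold change of -2.89 ± 0.18.

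Of 28 endoplasmic reticulum folding genes 24 rose and 1 fell (median 1.24, HSPA5, the chaperone BiP, 2.39 ± 0.21), and of 53 oxidative phosphorylation genes 40 rose (median 0.97, COX7A1 3.62 ± 0.27). Granule protein genes rose in 9 of 11 (median 3.95, BPI 4.53 ± 0.25), NADPH oxidase genes in 6 of 6 (median 2.92, CYBB 4.71 ± 0.44), ribosomal protein genes in 19 of 54 (median 0.50) and G2 and mitosis genes in 12 of 49, with 1 fall (median 0.32, CCNB2 2.10 ± 0.27). MHC class II genes fell in 8 of 11 (median -2.15), interferon genes in 5 of 13 (median -1.17, XAF1 -3.49 ± 0.53), stem cell genes in 7 of 12 with 1 rise (median -1.76, ADGRG1 -4.10 ± 0.31) and cytokine receptors in 5 of 9 (median -1.26, KIT -1.58 ± 0.25). Over the lists alone, 26, 42, 9, 6, 23 and 12 genes of the first 6 lists rose and 8, 7, 10 and 6 of the last 4 fell. Camera adjusted p were 9.12e-08, 4.85e-09, 2.18e-06, 0.000140, 0.000710, 0.0234, 0.000273, 0.000140, 0.000194 and 0.00854. With an estimated correlation, ribosomal proteins and G2 and mitosis had adjusted p = 0.713 and each of the other 8 lists had adjusted p = 0.448. DNA replication genes had a median of -0.06 and a mean of 0.03 beside a downward test (adjusted p = 0.805). With doublets kept, the MHC class II genes HLA-DQB2, DLA-DRA and CD74 turned to 1.04, 1.62 and 1.13. CHI3L1 and CCNB2 lost significance in DESeq2, and BPI with all 5 libraries. COX7A1, CAMP and CCNB2 did so at resolution 2.0 and with doublets kept, CCNB2 also without a block and CAMP also with at least 10 cells per sum. Altogether 1258 genes rose and 771 fell of 6411 (2586 unadjusted), and DESeq2 called 818, the fit without a block 749 and thinned sums 1080. With all 5 libraries 796 rose and 689 fell; 835 of the 2029 calls were kept and 38 turned direction, and with doublets kept 1353 were kept and 124 turned.

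Mature neutrophil-like cells had more granule, oxidase, inflammatory and glycolysis transcripts and fewer ribosomal protein and stem cell transcripts than HSPC-like cells. C3, complement component 3 (at least 45.9-fold), SLCO4C1, an organic anion transporter (at least 48.0-fold), INHBA, an activin chain (at least 35.5-fold), RAB3D, a secretory vesicle GTPase (at least 26.0-fold) and C11H5orf15 (at least 22.2-fold) had 0 counts in HSPC-like cells, and CAMP rose by 10.78 ± 0.45 on the log2 scale. The largest falls were PARP1, a DNA repair enzyme (-6.30 ± 0.31), DNTT (-6.23 ± 0.32), AKR1B1 (-5.60 ± 0.29), ITGA4, an integrin chain of marrow adhesion (-5.50 ± 0.29), the nucleolar NOLC1 (-4.91 ± 0.29) and GYPC (-4.76 ± 0.32). CD34 had a log2 fold change of -9.06 ± 0.38.

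Granule protein genes rose in 12 of 13 cases (median 8.03, or 7.80 with 2 genes at their bound; MMP9, gelatinase B, 8.03 ± 0.41), NADPH oxidase genes in 6 of 6 (median 5.58, CYBB 6.91 ± 0.45) and inflammatory genes in 6 of 6 (median 5.52, or 4.55 with 1 gene at its bound; CXCL8 6.14 ± 0.37, SOD2 4.89 ± 0.34). Glycolysis genes rose in 12 and fell in 4 of 17 (median 2.93, or 2.21 with 3 at their bound; GAPDH 3.47 ± 0.29). Immediate early genes rose in 10 and fell in 2 of 16 (median 3.36, KLF6 3.99 ± 0.32, HSPH1 -4.47 ± 0.36) and oxidative phosphorylation genes rose in 30 and fell in 2 of 53 (median 0.68). G2 and mitosis genes rose in 23 and fell in 3 of 49 (median 0.73, HMGB2 2.68 ± 0.28, HMMR 2.85 ± 0.30), while DNA replication genes fell in 20 and rose in 4 of 40 (median -0.87, HELLS -2.98 ± 0.27). Ribosomal protein genes fell in 39 of 54 (median -0.91, RPL4 -2.28 ± 0.25), stem cell genes in 9 of 10 with 1 rise (median -4.81), MHC class II genes in 9 of 11 with 1 rise (median -3.25) and interferon genes in 7 of 14 with 1 rise (median -1.12, DTX3L -3.79 ± 0.56). Adjusted over the list alone, 22 mitosis genes rose and the counts of the other 11 lists did not change.

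For mature neutrophil-like cells, camera adjusted p were 6.53e-07 for granule, 0.00110 for oxidase, 0.00224 for inflammatory, 0.0143 for glycolysis, 0.0248 for immediate early, 0.0143 for respiration, 0.0161 for mitosis, 0.0108 for DNA replication, 9.16e-06 for ribosomal, 0.000583 for stem cell, 0.00110 for MHC class II and 0.0240 for interferon genes. With an estimated correlation, respiration had adjusted p = 0.694, mitosis adjusted p = 0.794, DNA replication adjusted p = 0.586, ribosomal proteins adjusted p = 0.674 and each other list adjusted p = 0.562. C3, SLCO4C1, INHBA, RAB3D and C11H5orf15 lost significance in DESeq2, CAMP at resolution 2.0 and GAPDH without a block. In all 1819 genes rose and 1913 fell of 6557 (3981 unadjusted), against a median shift of all genes of 0.13; DESeq2 called 2273 and thinned sums 2123. Clusters 0 and 4 held most of the class in whole marrow 1 (1848 and 1539 of 4199 cells) and clusters 5 and 7 in whole marrow 3 (641 and 577 of 1610). Clusters 13 and 17 scored next for neutrophil progenitors. Their medians were 6926 and 6586 UMIs per cell, against 998 to 4307 in the other clusters of the class, so they weigh more in the sums. Which clusters carried the mitosis transcripts was not tested, so the rise cannot be assigned to mature neutrophils.

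Monocyte-macrophage-like cells had far fewer cell cycle transcripts than HSPC-like cells and more of antigen presentation, cytokine receptors, oxidase and interferon response. SULF2 (at least 77.5-fold), MYOF, myoferlin (at least 42.3-fold), HNMT, which methylates histamine (at least 37.4-fold), XDH, xanthine dehydrogenase (at least 37.1-fold), CSF1R, the receptor of macrophage colony-stimulating factor (at least 22.4-fold) and FGD2 (at least 21.7-fold) had 0 counts in HSPC-like cells. TFPI, tissue factor pathway inhibitor, had 0 counts in monocyte-macrophage-like cells and was at least 198-fold lower. DNTT (-7.46 ± 0.30), CLSPN (-5.61 ± 0.36), TOP2A, topoisomerase II alpha (-5.52 ± 0.22), the nucleoside transporter SLC29A1 (-5.48 ± 0.35) and GYPC (-5.02 ± 0.31) fell most among the others. CD34 had 2 counts against 412, a ratio of 1002 (counting interval 275.6 to 8299).

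DNA replication genes fell in 34 of 34 cases (median -3.92, TYMS -4.54 ± 0.22), G2 and mitosis genes in 37 of 43 with 2 rises (median -2.64), ribosomal protein genes in 46 of 54 (median -0.67) and stem cell genes in 8 of 11 with 1 rise (median -2.79). Cytokine receptors rose in 12 and fell in 3 of 15 (median 2.59, or 2.53 with 5 genes at their bound) and MHC class II genes rose in 8 and fell in 2 of 12 (median 2.32, CTSS, cathepsin S, 6.11 ± 0.22, DLA-DRA 2.99 ± 0.17). Interferon genes rose in 10 and fell in 1 of 17 (median 1.30, MX2 4.21 ± 0.29), NADPH oxidase genes rose in 5 of 6 (median 3.63, CYBB 6.15 ± 0.35), granule genes in 8 of 8 (median 3.57, LTF 4.72 ± 0.19), inflammatory genes in 5 of 5 (median 2.73, CXCL8 4.44 ± 0.25), immediate early genes in 10 of 16 with 1 fall (median 2.20, FOS 4.04 ± 0.35) and glycolysis genes in 9 of 14 with 3 falls (median 1.74, ENO1 2.48 ± 0.16). Over the lists alone, 34, 38, 46 and 8 genes of the first 4 lists fell, and 12, 8, 11, 5, 8, 5, 10 and 10 of the other 8 rose. Camera adjusted p were 8.28e-14, 1.16e-09, 1.61e-06, 0.00342, 0.00651, 0.0193, 0.00323, 0.00230, 0.000252, 0.00751, 0.00230 and 0.0497. SULF2, MYOF, XDH, HNMT and CSF1R lost significance in DESeq2, LTF and CXCL8 at resolution 2.0, LTF also with doublets kept or at least 10 cells per sum, and FOS without a block. The glycolysis list did not pass with RLE factors (adjusted p = 0.0524). RNA released by neutrophils was not tested as a source of the granule transcripts in this comparison. Cluster 11 held 405 of 467 cells of the class in whole marrow 1 and 209 of 236 in whole marrow 3. It scored 2.208 for monocyte-macrophages and 2.107 for mature neutrophils, and its leading markers decided its name. The granule, oxidase and inflammatory rises therefore cannot be assigned to monocytes alone. In whole marrows 1 and 3 the median was 5035 and 8759 UMIs per monocyte-macrophage-like cell, against 15020 and 23720 per HSPC-like cell. Ribosomal proteins had adjusted p = 0.647 and each of the other 11 lists adjusted p = 0.439 with an estimated correlation. Signs differed, without passing the threshold, for heme (median -0.28, mean 0.17, test down) and red cell skeleton genes (0.09, -0.74, down). In total 1331 genes rose and 1631 fell of 5539 (3188 unadjusted), and DESeq2 called 1239.

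Pro-B or pre-B-like cells had more mitosis and fewer ribosomal protein and stem cell transcripts than HSPC-like cells. RAG1, the recombinase of antigen receptor genes (at least 12.4-fold), and E2F2, a cell cycle transcription factor (at least 13.8-fold), had 0 counts in HSPC-like cells. CDKN3 had 311 counts against 3 (ratio 30.4, counting interval 10.3 to 148). MCUB, of the mitochondrial calcium uniporter (4.34 ± 0.40), APLP2 (4.22 ± 0.59) and IL7R, the interleukin-7 receptor (3.29 ± 0.39), also rose. TFPI (1 count against 122, ratio 415.7 lower, counting interval 73.2 to 16554), NAV3 (3 against 82, ratio 93.1 lower, 30.8 to 461), CCND2, cyclin D2 (-5.90 ± 0.66), KIT (-5.47 ± 0.49), ADGRG1 (-5.36 ± 0.55) and MSRB3 (-5.16 ± 0.64) fell most. CD34 had a log2 fold change of -2.30 ± 1.33.

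G2 and mitosis genes rose in 35 of 48 cases (median 1.84, CDC20 2.30 ± 0.28) and DNA replication genes in 6 of 37 (median 0.45, UHRF1 2.43 ± 0.27). Ribosomal protein genes fell in 52 of 54 (median -0.92, RPL18 -1.35 ± 0.13), and stem cell genes fell in 4 and rose in 1 of 8 (median -2.83, MLLT3 -3.28 ± 0.53). Over the lists alone 41 and 6 rose, and 52 and 5 fell. Camera adjusted p were 6.83e-17, 0.00451, 1.95e-14 and 0.00261, and each of the 4 lists had adjusted p = 0.952 with an estimated correlation. V(D)J recombination genes rose in 2 of 9 cases (median 0.26, camera adjusted p = 0.0835). The camera test, median and mean of cholesterol synthesis genes differed in sign (down, -0.06 and 0.07; adjusted p = 0.941). In all, 277 genes rose and 526 fell of 4715 (1355 unadjusted). The count was 245 with DESeq2, 229 without a block, 469 with thinned sums and 3026 with all 5 libraries. RAG1 and E2F2 lost significance in DESeq2 and without a block, CDKN3 and CCND2 in DESeq2, MCUB without a block and IL7R at resolution 2.0. CDC20 lost significance with doublets kept and turned to -0.09 at resolution 2.0.

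**Figure D4:**
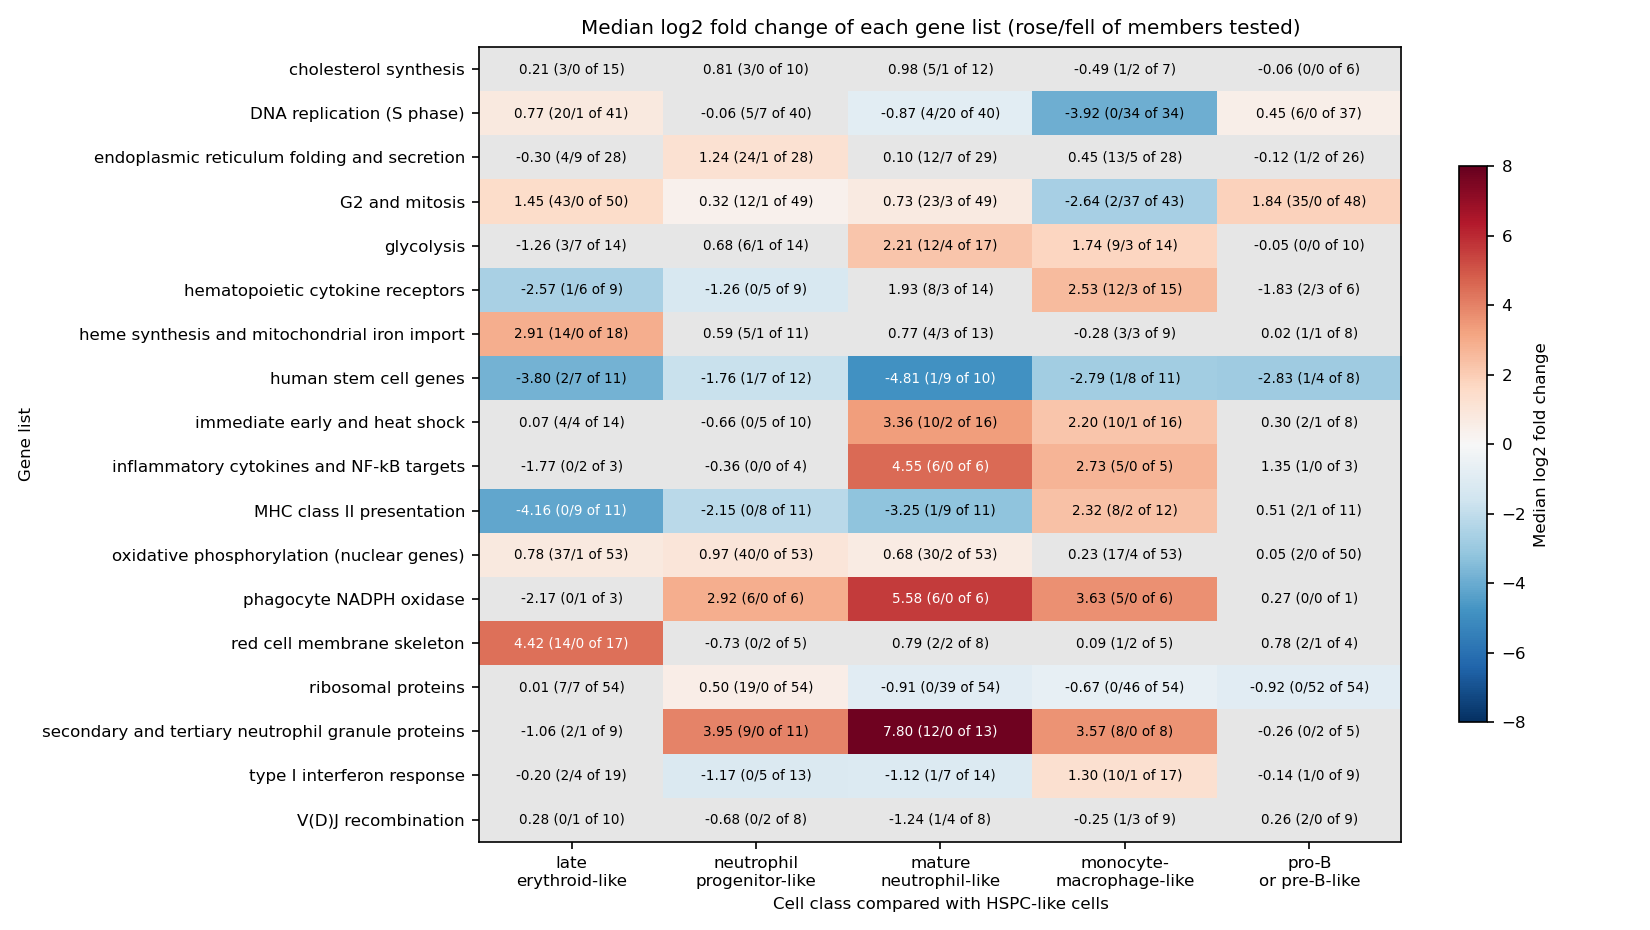
Median log2 fold change of each gene list (rows) in 5 cell classes against HSPC-like cells of whole marrows 1 and 3 (columns), with the numbers of members that rose and fell; colour marks lists past the camera test at the preset correlation, grey the others, and genes at 0 counts in a class stand at their bound. Granule protein genes reach 7.80 in mature neutrophil-like cells, and DNA replication genes -3.92 in monocyte-macrophage-like cells.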

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

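The tests of 1 library deciding the immediate early difference and of 1 source of free RNA were chosen only after the results were seen.

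The difference between neutrophil progenitor-like and HSPC-like cells was not the same in sorted and unsorted marrow: it differed for 1577 of 8817 genes (428 larger and 1149 smaller in sorted libraries; 2457 at an unadjusted p under 0.05; edgeR quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, 4 libraries, 2 residual degrees of freedom). For pro-B or pre-B-like cells it differed for 4 of 8569 genes (374 unadjusted), all smaller in sorted libraries: LTF (-3.68 ± 0.32 SE, adjusted p = 0.000422), IFI30 (-3.70 ± 0.38, adjusted p = 0.00123), TSPAN2 (-4.00 ± 0.53, adjusted p = 0.0137) and MGST1 (-3.61 ± 0.53, adjusted p = 0.0293), named after their values were seen. These results are given here because a test found a difference between the groups' effects. The 4 libraries were the sorted ones, from marrows 2 and 3, and whole marrows 1 and 3, so sort and dog cannot be told fully apart.

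For neutrophil progenitor-like cells, different clusters on either side of the sort could account for the difference. With only the cluster led by MPO, which both groups share, 5 of 8464 genes differed (583 unadjusted), against 1234 with the whole class thinned to the same totals, a ratio of 0.00405. This cluster was drawn from expression in these same data, so its cells are alike in both groups by construction. It held 71 and 34 cells in whole marrows 1 and 3, and thinning matched UMIs but not cells. The lower count therefore cannot decide between different clusters and other causes. Free RNA in whole marrow that reached both classes alike is argued against as the cause of the whole difference. The 1149 genes had a median log2 difference of -1.05 in this class, which is enlarged because they were chosen by it. The 1141 of them tested in pro-B or pre-B-like cells had a median of -0.17 there (quartiles -0.46 and 0.04). Both values are relative to HSPC-like cells of the same libraries, so free RNA shared with those cells cancels in part. Free RNA that reached the classes unequally was not tested. For LTF, TSPAN2 and MGST1 free RNA stays open, since they were lower by about as much or more in pro-B or pre-B-like cells (given above) as in neutrophil progenitor-like cells (-4.39, -3.91 and -2.32). A true effect of CD34 level on progenitor state stays open as untested.

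SLPI, CAMP, ELANE, HBM, AHSP and ENSCAFG00000032615 were lower in sorted than in whole-marrow HSPC-like cells, though without whole marrow 1 only SLPI and CAMP of the 6 passed the test. RNA released by neutrophils and red cells may be their source: the median log2 ratio of UMIs per cell between HSPC-like and lymphoid cells of the same libraries was -0.495. From the share of cells with a UMI, the ratio of HSPC-like to lymphoid rates lay between 1.30 and 1.78 over the 6 genes, highest over lowest 1.37, while ratios of mean UMIs spread from -1.90 (ELANE) to 0.58 (ENSCAFG00000032615) on the log2 scale. Doublets with neutrophils or red cells as the whole cause are argued against, since 100% of the 47 HSPC-like cells, and 97.6% of lymphoid cells, held a UMI of these genes. Low expression by the HSPC-like cells themselves was not tested.

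Immediate early and heat shock genes were higher in sorted HSPC-like cells as a set in camera at the preset correlation (adjusted p = 0.00661). None of the 18 members passed the test over all genes. No list passed in this comparison with an estimated correlation or with fry. Handling during the sort could raise them. Their median log2 fold change was 0.72 in sorted pro-B or pre-B-like cells (camera adjusted p = 0.0722). It was 0.72 in neutrophil progenitor-like cells (camera adjusted p = 0.407), and neither passed the threshold. These classes differed in their clusters between sorted and whole-marrow libraries, so their medians cannot tell handling from a change in clusters. Handling therefore stays open. Sorted library 1 may decide the size, since the median over 18 genes was 0.53 without it and 1.47 with all 4 libraries, but with all libraries kept it was also lower at resolution 2.0 (0.84, 10 genes), with doublets kept (0.84, 11 genes) and with at least 10 cells per sum (0.86, 10 genes). A biological difference between CD34-positive cells and the rest of the class was not tested.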

How the results depend on the processing

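The fits with at least 10 cells per sum, with at most 20% mitochondrial UMIs and with HSPC-like sums thinned, and the blocked list tests, were chosen only after the results were seen.

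Counts were held to be the same within 1.5 times, and class shares if their direction held, whatever their size. By these rules, of 253 alternatives for class shares, gene counts and list counts, 212 stayed the same, 38 moved a count and 3 turned a share's direction. Class shares kept their direction in 126 of 129. Settings in which a class was not named were left out of this count. A class named in only some libraries counted as 0 in the others, so a kept direction can come from naming. With each library clustered alone, whole marrow had no named HSPC-like cells. The neutrophil progenitor-like difference turned to -5.68 points at resolution 0.5 and -0.299 points with each library clustered alone. The basophil or mast-like difference turned to 10.8 points at resolution 2.0. Over the 7 comparisons 267 gene results are named, with genes named in several comparisons counted in each. Of their 3375 alternatives, 3215 left the direction and the side of the threshold, called or not, 120 lost a call, 29 gained one and 11 turned direction. The cause was not tested for any of these unless stated.

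Leaving out 1 library gave 1698 to 4519 genes over all cells and 11 to 71 genes within HSPC-like cells, where a lone library is assumed to vary like the others. Within HSPC-like cells, DESeq2 called 31 genes, no low-count filter 135, resolution 2.0 13 and doublets kept 12. In the class comparisons DESeq2 called 1483 (late erythroid-like), 818 (neutrophil progenitor-like), 2273 (mature neutrophil-like), 1239 (monocyte-macrophage-like) and 245 genes (pro-B or pre-B-like). Thinned sums, which test fewer genes, gave 1514, 1080 and 2123 genes for late erythroid-like, neutrophil progenitor-like and mature neutrophil-like cells and 469 for pro-B or pre-B-like cells. All 5 libraries gave 3026 genes in pro-B or pre-B-like cells. With an estimated correlation 0 lists passed in each of the 7 comparisons; with fry, 0 passed for HSPC-like, late erythroid-like, monocyte-macrophage-like and pro-B or pre-B-like cells, 2 for neutrophil progenitor-like and 5 for mature neutrophil-like cells.

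The dog as a block gave 5544 genes over all cells, and a block by title number 1677. Within HSPC-like cells, with at least 10 cells per sum, the count was 53 with the dog as a block and 7 without it. In that fit CD34 turned to a log2 fold change of -0.083 and MEIS1 to -0.10 (-0.047 with title numbers). Without the block, 1527 genes were called for late erythroid-like, 749 for neutrophil progenitor-like and 229 for pro-B or pre-B-like cells.

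With doublets kept, HLA-DQB2, DLA-DRA, CD74, SAMD9L and CDC20 turned to 1.04, 1.62, 1.13, 0.76 and -0.00182 in neutrophil progenitor-like cells, and HELLS to 0.0089 within HSPC-like cells. At resolution 2.0 CDC20 turned to -0.35 in neutrophil progenitor-like and -0.091 in pro-B or pre-B-like cells.

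Not run were the HSPC-like and class comparisons at resolution 0.5 and the HSPC-like one with each library clustered alone, where whole marrow had no named HSPC-like cells. Also not run were the HSPC-like block at 20 cells per sum (0 residual degrees of freedom), all 5 libraries for late erythroid-like, mature neutrophil-like and monocyte-macrophage-like cells (fewer than 20 sorted cells) and leaving out a library in the class comparisons at 20 cells per sum, which have 2 pairs. With at least 10 cells per sum, the counts without whole marrow 1 and without whole marrow 3 were 2509 and 2436 for late erythroid-like, 1902 and 1673 for neutrophil progenitor-like, 3707 and 3460 for mature neutrophil-like, 2831 and 2834 for monocyte-macrophage-like and 877 and 746 for pro-B or pre-B-like cells. The total of UMIs limits how many genes can be tested: with sums thinned to the smallest total, the HSPC-like comparison tested 4050 genes in place of 9312 and called 5. HSPC-like cells of whole marrow are few, 47 cells in the 2 libraries used.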

Other observations

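The tests within cluster 16 and of the sort within each class were chosen only after the results were seen.

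Cluster 16, which stayed unnamed, made up 7.91% ± 1.97 SD of sorted cells (n = 2) and 0.335% ± 0.0639 of whole-marrow cells (n = 3). Its marker score was highest for basophils and mast cells (2.369, 6 of 7 markers at 2-fold or more), then for erythroid progenitors (1.802). Its leading genes included FCER1A, listed for basophils and mast cells, and ITGA2B and SELP, listed for megakaryocytes. Against HSPC-like cells of the sorted libraries, EPOR, the erythropoietin receptor (6.97 ± 0.17 SE), KCTD1 (4.03), UCHL1 (3.04) and MICAL3 (2.81) were higher on the log2 scale, and TFEC (-3.53), DLA-DRA (-3.43), HSPB1 (-3.27) and HOPX (-3.15) lower; these genes were named after their values were seen. In all, 1364 genes were higher and 1235 lower of 8360 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 3261 unadjusted; 2 library pairs, 1 residual degree of freedom). G2 and mitosis genes rose in 41 of 49 cases (camera adjusted p = 1.32e-14), heme synthesis genes in 8 of 16 (0.000316), interferon genes in 12 of 21 (0.000316), DNA replication genes in 11 of 41 with 3 falls (0.00282), oxidative phosphorylation genes in 14 of 53 with 1 fall (0.0173) and red cell skeleton genes in 7 of 11 with 3 falls (0.0256). Immediate early and heat shock genes fell in 15 of 18 with 2 rises (0.000235), MHC class II genes in 9 of 12 (0.000316), NADPH oxidase genes in 7 of 7 (0.00284) and stem cell genes in 9 of 19 with 3 rises (0.0398). With an estimated correlation MHC class II had adjusted p = 0.517 and each of the other 9 lists adjusted p = 0.426.

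G2 and mitosis genes were lower in sorted than in whole-marrow cells of 3 classes: the median log2 fold change was -0.80 in HSPC-like, -0.39 in pro-B or pre-B-like and -1.26 in neutrophil progenitor-like cells (camera adjusted p = 7.58e-12, 5.72e-09 and 4.65e-16). Single members passed in 0 of 49, 0 of 50 and 33 of 49 cases. Interferon genes had medians of 0.58, 0.49 and 1.07 (0.0170, 0.0245 and 0.00433), with 0 of 20, 0 of 15 and 5 of 18 members past the test. In HSPC-like cells with at least 10 cells per sum, the interferon list had adjusted p = 0.723, and with the dog as a block it turned downward (adjusted p = 0.662). The mitosis, interferon and granule lists had adjusted p = 0.513 with an estimated correlation in HSPC-like cells, and that test was not run for the sort within the other 2 classes. Neutrophil granule genes were lower in the same 3 classes, with medians of -5.80, -6.15 and -7.98 and 2 of 6, 3 of 6 and 12 of 12 members down (camera adjusted p = 6.46e-08, 5.63e-19 and 6.21e-14). Single genes differed with the sort for 15 of 7136 in pro-B or pre-B-like cells (0 higher) and for 833 higher and 1201 lower of 9403 in neutrophil progenitor-like cells. The dog was not a block in these fits, though sorted and whole-marrow libraries share dogs, and no blocked fit is reported for these 2 classes. All 3 classes differ in their clusters between libraries: cluster 24 held 113 of 1208 and 26 of 747 HSPC-like cells in the sorted libraries and 10 of 27 and 2 of 20 in whole marrows 1 and 3. Cluster 19 held 25 of 2027 and 216 of 1504 pro-B or pre-B-like cells in the sorted libraries and 19 of 174, 12 of 49 and 87 of 114 in whole marrow. Neutrophil progenitor-like cells were mostly of cluster 2 in sorted libraries and of cluster 8 in whole marrow.

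Mature neutrophil-like cells made up 61.2%, 42.0% and 38.4% of kept cells in whole marrows 1 to 3, and 62.0%, 55.6% and 56.0% with cluster 6 added. The protocols require under 25% neutrophils by flow cytometry, and the cells over which that share was taken are not given in the sources used here. Cluster 18, led by CD3E, CCL5 and GZMK, was 2.89% ± 0.729 of whole-marrow cells and 0.0495% of sorted cells. Cluster 26, led by GATA3 and IL17RB, was 0.649% ± 0.172 of sorted and 0.101% ± 0.0499 of whole-marrow cells.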
